A study of Homo sapiens with 4 samples.

How the data were processed

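RNA was extracted with TRIzol from unstimulated cultures, treated with DNase and sequenced after standard Illumina library preparation, per the labels' protocols, which name neither the kit nor whether it marks strand. Reads were trimmed with fastp 0.19.4, aligned with STAR 2.5.3a to the human genome hg19 and counted with tools of SAMtools 1.6 and Subread 1.6.2, per the submitters' processing notes. The strand setting and the annotation release are not given in the sources used here. The deposited counts are whole numbers of reads for 48104 RefSeq transcripts, 38046 coding (NM) and 10058 noncoding (NR), of 25680 gene symbols, 1 file per library. The deposited FPKM values equal the count divided by the transcript length and by the summed counts of the file, and the length this gives is a whole number for 100% of the transcripts with counts, within 0.001. The deposited TPM values (transcripts per 1e6) are length-scaled values that sum to 1000000 in each file. Only the counts were used in the comparisons.

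A read was counted in each transcript that it overlaps: of 1661 genes with more than 1 transcript and at least 40 reads, 576 (34.7%) had the same count in all transcripts. The count of a gene was therefore taken as the highest count of any of its transcripts, in which a read enters at most once. The plan made before the data were examined was to sum transcripts, which counts a read several times. The change was made after the files were seen and before any test was run. The called genes, the named genes, the list tests, the line-selective genes and the similarity were also computed with the planned sum, and the list percentiles and the splits of the libraries were not. Transcript counts summed to 585445 in MCF-7, 524672 in MMNK-1, 603014 in T-47D and 691620 in ZR-75-1, and gene counts to 334468, 302807, 337831 and 401167.

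Genes on the opposite strand were found with bedtools 2.31.1 in the GENCODE 29 annotation, as protein-coding exons that overlap the exons of a gene by at least 50 bp, after older symbols had been matched (25049 symbols, 97.5%). That annotation is of another build (GRCh38) than the files, so it was used only for which genes overlap or neighbour each other, and no coordinates are given.

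MMNK-1 was compared with the 3 breast lines in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, libraries scaled with TMM factors, and the quasi-likelihood F test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 2 residual degrees of freedom, from 3 different breast lines, and the lone MMNK-1 library is assumed to vary like them. The spread of a gene was moderated toward that of all genes, with 7.44 prior degrees of freedom. A p therefore measures the difference against a spread between breast lines that is mostly borrowed from other genes. It does not measure the spread between cultures of a line. The common biological coefficient of variation was 0.649. Fold changes against a group without counts are given as bounds with a floor of 3 counts per library, and other ratios are of pooled counts with exact 95% intervals. CPM are scaled by TMM factors. Intervals and floors cover counting error only.

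Before the data were examined, 28 gene lists were fixed from general knowledge of the tissues. Many members had too few counts for a test. Tested were 11 of 40 mesenchymal, 10 of 40 extracellular matrix, 15 of 28 YAP and TGF-beta responsive and 4 of 38 receptor tyrosine kinase genes. In the lower lists 18 of 35 epithelial junction, 20 of 32 luminal, 23 of 37 oestrogen-responsive and 14 of 39 biliary genes were tested. The 24 lists with at least 3 tested members were tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 and a prior count of 2, adjusted over the lists, and again with an estimated correlation. With the preset, the p rests on the number of genes and not on replicate libraries. An estimated correlation limits it to the 2 residual degrees of freedom. The genes named were set by a rule written at the same time. They are the 10 protein-coding genes with the largest fold change in each direction among those past the threshold, with a mean of 20 CPM or more in the higher group and MMNK-1 outside the range of the breast lines. They are also 16 fixed markers, members of each list chosen by adjusted p or by size of change, and the 6 line-selective coding genes with the largest ratio for each breast line. Not every list member that the rule names is printed. Other names fall outside the rule, among them ACTB, GAPDH and EEF1A1, given as examples, and rows opposite list members.

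No test was made among the breast lines, which have 1 library each. A gene was called line-selective with at least 10 CPM and 8 times the CPM of the higher of the other breast lines, with libraries under 3 counts set to 3. Lists of at least 5 tested members were placed by the percentile of their median among 10000 random lists matched on mean expression, in 20 bins. Similarity was Pearson's r of log2(CPM + 1).

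The edgeR and camera tests, the line-selective rule, the similarity and the list percentiles were run first on simulated libraries with the mean breast levels and the sizes of the real ones and 200 genes changed by known folds. For edgeR and camera every gene was given the common dispersion. For the others the simulated lines differed by counting noise alone, and changed genes had a mean of 10 or more counts. The counts of rows and pairs given in the closing section were not simulated. Among 4835 simulated genes the edgeR test recovered 3%, 61% and 97% of genes raised 4-, 16- and 64-fold in the lone library and 0%, 6% and 23% of those lowered, with at most 4 false calls. The line-selective rule, over 25680 genes, found 0% of 4-fold and 100% of 16- and 64-fold changes. A rule set at 8 times gives this where lines differ by counting noise alone, so it does not show how the rule does on real lines. Alternatives were other scaling factors, filters and tests (with DESeq2 1.42.0 among them), thinned counts, transcripts as deposited, each breast line left out, other ratios and pseudocounts, the sum over transcripts that had been planned as the main value and, chosen after the data were seen, the omission of genes opposite coding exons. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.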

Results

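Gene expression was measured by RNA sequencing in unstimulated cultures of 4 human cell lines, with 1 library for each line. The breast cancer lines MCF-7, T-47D and ZR-75-1 are luminal lines that express the oestrogen receptor. MMNK-1 is a line of cholangiocytes, the epithelial cells of the bile duct, that was immortalised with the SV40 large T antigen and telomerase. The comparison that the design gives is that of the cholangiocyte line with the 3 breast cancer lines, and the breast lines can also be set side by side. Gene counts summed to 334468 in MCF-7, 302807 in MMNK-1, 337831 in T-47D and 401167 in ZR-75-1. At least 10 counts were found for 3163 of the 25680 gene symbols in MCF-7, 2916 in MMNK-1, 3215 in T-47D and 3584 in ZR-75-1. A count of 3, used below as the floor for a library without counts, was worth 9.73 CPM (counts scaled to the library size) in MCF-7, 10.5 in MMNK-1, 9.14 in T-47D and 7.93 in ZR-75-1. The error given with a breast mean is the SD over 3 different lines, and intervals on counts cover counting error only. MMNK-1 had no replicate, and by the labels it was grown in another medium than any of the breast lines, so cell line, tissue and medium cannot be separated.

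The counts lay mostly on rows of genes whose exons overlap a protein-coding gene of the opposite strand. Of the 25049 symbols found in the annotation, 3981 (15.9%) had such an overlap of at least 50 bp. These rows held 75% of the counts in MCF-7 (95% Wilson interval 74.8 to 75.1), 77.3% in MMNK-1 (77.1 to 77.4), 75% in T-47D (74.9 to 75.1) and 77.5% in ZR-75-1 (77.4 to 77.6). Genes that every cell uses had few counts. The row of ACTB, the cytoskeletal actin, held 51 to 99 counts per library, that of the glycolytic enzyme GAPDH 13 to 68, and that of the translation factor EEF1A1 52 to 60. The median of 47 cytosolic ribosomal protein rows was 11 counts in MCF-7, 8 in MMNK-1, 9 in T-47D and 10 in ZR-75-1. In KRT8, the transcript with exons opposite KRT18 held 55913 counts over the 4 libraries, and none of its transcripts without such exons held more than 675. The row of VIM held 30 counts in MMNK-1, where that of VIM-AS1, which lies opposite VIM, held 9975. Whether the counting used strand is not given in the sources used here. Rows are therefore named as deposited, with the opposite coding gene where there is one, and a value of such a row cannot be assigned to the named gene rather than the opposite one. For rows without an opposite coding gene, such as those of TERT, PIM1, CD24, ESR1, PGR and most list members, it is likewise not known whether the reads came from the strand of the named gene, so all values below are counts on the row of that name and not established expression of the gene.

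MMNK-1 differed more from each breast line than the breast lines differed from each other. Pearson's r of log2(CPM + 1) across 4835 genes was 0.734 between T-47D and ZR-75-1, 0.688 between MCF-7 and ZR-75-1 and 0.673 between MCF-7 and T-47D. With MMNK-1 it was 0.526 for ZR-75-1, 0.518 for T-47D and 0.49 for MCF-7. On average 681 genes differed at least 4-fold between breast lines (SD 33.5 over 3 pairs), against 1003 between MMNK-1 and a breast line (SD 50.1 over 3 pairs). These coefficients are across genes, which are not independent replicates, and no test was made of them.

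The list of mesenchymal genes had 6 tested rows opposite its members, of which 5 were higher in MMNK-1 and 4 past the threshold. The exceptions were ZEB2-AS1, opposite ZEB2, which was higher without passing (edgeR adjusted p = 0.21), and ACTA2-AS1, opposite ACTA2, with 3 counts in MMNK-1 and 56, 86 and 9 in MCF-7, T-47D and ZR-75-1 (edgeR adjusted p = 0.306). Of the 4, the row of VIM-AS1, opposite the intermediate filament gene VIM, reached 35000 CPM in MMNK-1 against 25.1 ± 8.32 (SD, n = 3 lines) in the breast lines, a ratio of pooled counts of 1366 (95% interval 931.7 to 2092; edgeR quasi-likelihood adjusted p = 7.56e-05). LOC100507156, opposite the lysyl oxidase gene LOXL2, had 4087 CPM against 4.94 ± 1.75, CTB-113P19.1, opposite the matrix glycoprotein gene SPARC, 2772 CPM against 2.98 ± 0.304, and PCSK7, opposite the actin-binding protein gene TAGLN, 4614 CPM against 12.3 ± 7.82. Outside that list, the row of KRR1, opposite GLIPR1, had 3901 CPM against 34.6 ± 9.56, and that of C10orf55, opposite the urokinase gene PLAU, 1235 CPM against 10.8 ± 1.25. In the other direction NFATC3, which lies opposite the epithelial splicing regulator gene ESRP2, had 10.5 CPM in MMNK-1 and 3150 ± 831 in the breast lines, a ratio of 304 (95% interval 104.1 to 1477; edgeR adjusted p = 0.00398). The row of ESRP2 itself was not lower (log2 fold change 0.103, edgeR adjusted p = 0.976). The rows of this paragraph except NFATC3 were chosen after their values were seen. LOC100507156, CTB-113P19.1, PCSK7, C10orf55 and ZEB2-AS1 had at most 8 counts in any breast line. They passed the filter on MMNK-1 alone, so their direction was fixed by it. NFATC3, with 3 counts in MMNK-1, likewise passed on the breast lines alone. VIM-AS1, LOC100507156, CTB-113P19.1, PCSK7, KRR1, C10orf55 and NFATC3 passed on summed transcripts as well.

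In all, 88 of 4835 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 64 higher and 24 lower in MMNK-1, and 658 had an unadjusted p under 0.05. Of the 64, 28 lay opposite a coding exon, as did 13 of the 24. Among all 4835 tested genes 2009 did, a share near that of the 88, so the called genes do not stand out in this. The counts were 0 in all 3 breast lines for 17 of the higher genes and 0 in MMNK-1 for 12 of the lower ones. Such genes passed the filter on the higher group alone, which fixed their direction. For the 17 the breast lines gave no spread of their own, so their p rests on that of other genes. When the transcripts of a gene were summed, as had been planned, 16 genes passed, 13 higher and 3 lower, and all 16 were among the 88. Without MCF-7 411 genes passed, without T-47D 162 and without ZR-75-1 204, whereas limma-voom called 2. In simulated libraries of the same depth, with the common dispersion for every gene, the test recovered 97% of genes raised 64-fold in the lone library. It recovered 61% of those raised 16-fold and 3% of those raised 4-fold. It recovered 23%, 6% and 0% of genes lowered by the same folds, so the numbers of higher and lower genes are not comparable.

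**Figure D1:**
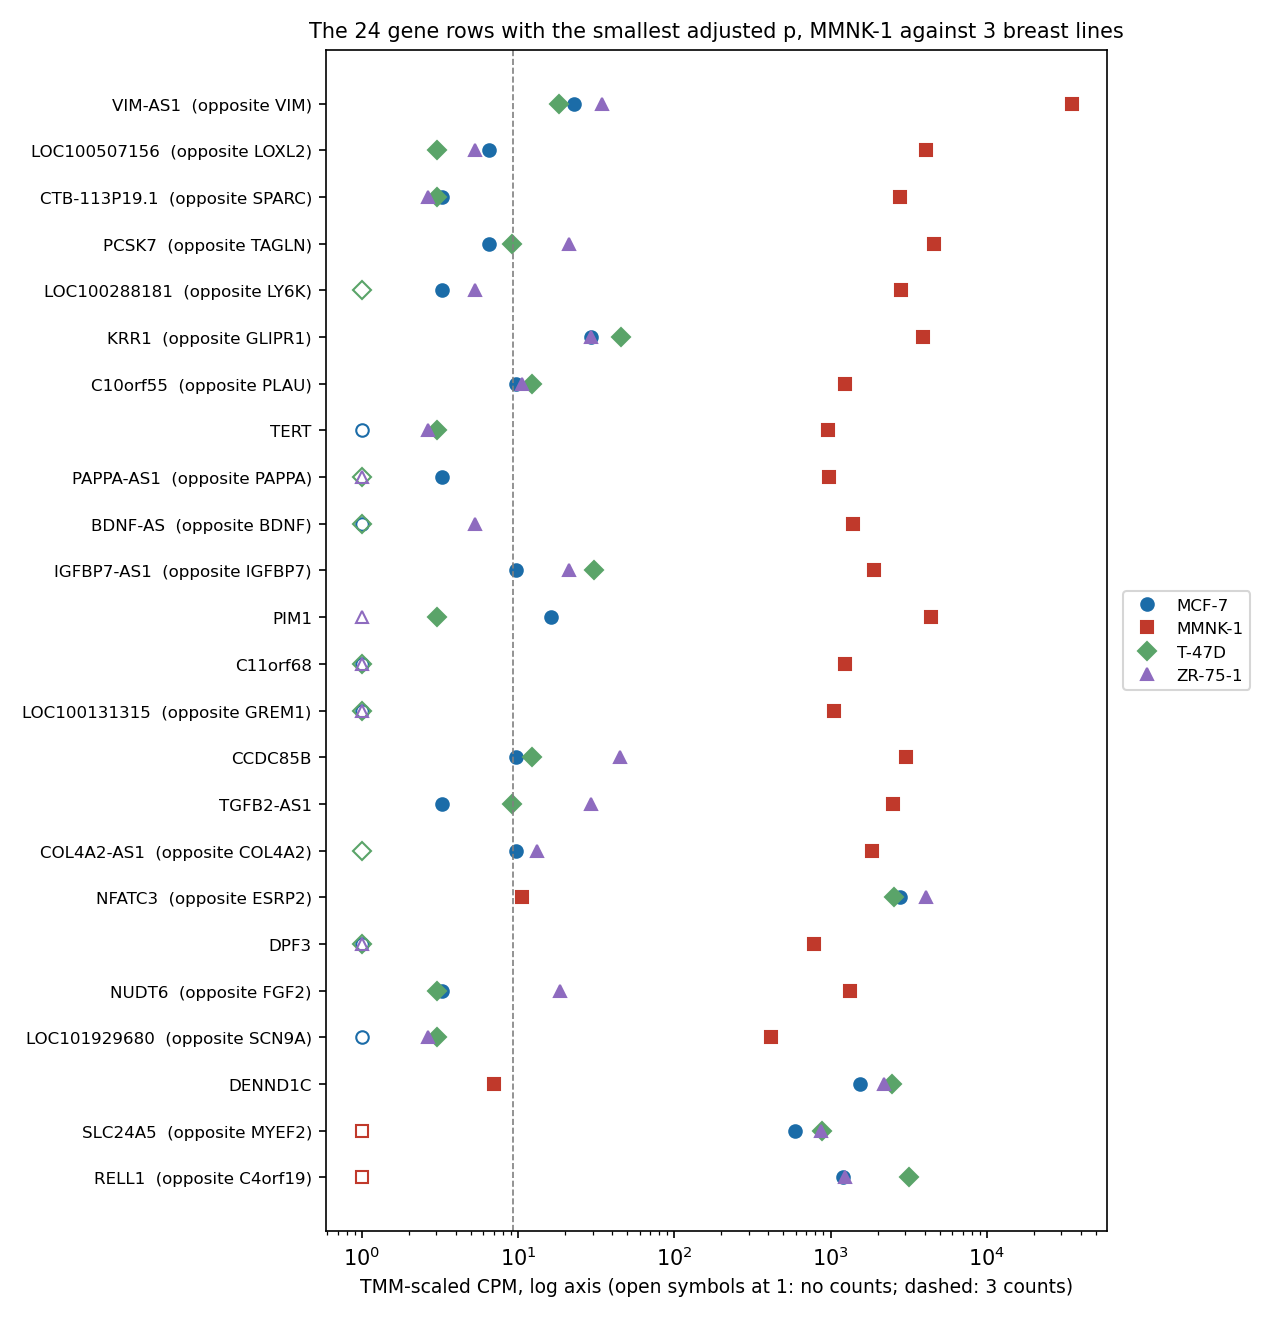
TMM-scaled CPM (log axis) in each of the 4 libraries for the 24 gene rows with the smallest adjusted p, with the coding gene on the opposite strand in brackets. MMNK-1 (squares) lies above the breast lines in all but NFATC3, DENND1C, SLC24A5 and RELL1, and open symbols mark libraries without counts.

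Rows of protein-coding genes with the largest increases in MMNK-1 included that of the telomerase gene TERT. It had 276 counts in MMNK-1, 1 in T-47D, 1 in ZR-75-1 and 0 in MCF-7, a ratio of 491 (95% interval 134.7 to 4077; edgeR adjusted p = 0.00227, and 0.0363 on summed transcripts). MMNK-1 was immortalised with telomerase, so reads of an introduced TERT sequence cannot be told apart here from those of the line's own gene. The kinase gene PIM1 reached 4386 CPM against 6.42 ± 8.62 in the breast lines (edgeR adjusted p = 0.00277), but missed the threshold on summed transcripts (0.0565). C11orf68 and DPF3, a gene of a chromatin remodelling subunit, had 353 and 223 counts in MMNK-1 and none in the breast lines, which makes them at least 138.6-fold and 87.6-fold higher against a floor of 3 counts per library, and both passed on summed transcripts. NPPB, GPR17, HS3ST5, LAYN, AKAP2 and the actin-binding CALD1 were also without counts in the breast lines and at least 16.5-fold higher, up to at least 34.96-fold for the natriuretic peptide gene NPPB, but did not pass on summed transcripts. GPR17 lies opposite LIMS2, and AKAP2 had the same counts as PALM2-AKAP2, with which it shares reads.

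Among coding genes lower in MMNK-1, CD24, a surface glycoprotein of epithelial cells, had 191 ± 36.5 CPM in the breast lines and no counts in MMNK-1, at least 18.2-fold lower (edgeR adjusted p = 0.0345, and 0.0459 on summed transcripts). DENND1C had 2071 ± 479 CPM against 7.02, a ratio of 297 (95% interval 82.2 to 2458), and also passed on summed transcripts. RELL1, opposite C4orf19, was at least 178.7-fold lower and SLC24A5, opposite MYEF2, at least 74.4-fold. GRIN1, CPLX1, KAAG1, SRMS and FMN1, each without counts in MMNK-1, were at least 15.05-fold lower, up to at least 52.1-fold for the NMDA receptor gene GRIN1. KAAG1 lies opposite DCDC2. KRT8, on the transcript opposite KRT18, had 9364 CPM in MMNK-1 and 51820 ± 11850 in the breast lines, a ratio of 5.60 (95% interval 5.389 to 5.827; edgeR adjusted p = 0.0478). KRT8 missed the threshold in 8 of 14 alternative settings, with edgeR or limma adjusted p of 0.0512 to 0.218, among them that without ZR-75-1 (0.0582) and that on summed transcripts (0.142). RELL1, SLC24A5, GRIN1, CPLX1, KAAG1, SRMS and FMN1 also missed it on summed transcripts.

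Gene lists fixed in advance fell into 4 that were lower and 6 that were higher in MMNK-1 than other genes were (camera with a preset correlation). The lists share tested members, so they are not separate lines of evidence. PGR, TFF1, XBP1, BCL2 and CA12 are both luminal and oestrogen-responsive, and EPCAM and CLDN4 both biliary and junctional. SERPINE1 and AXL are in the mesenchymal and the YAP and TGF-beta lists, and AXL is also among the kinases. With the preset, the p of a list rests on the number of genes and not on replicate libraries. With an estimated correlation none passed, the smallest being adjusted p = 0.257. In the mesenchymal list all 11 tested members had higher values in MMNK-1, 3 of them past the threshold over all genes and 9 adjusted over the list alone (camera adjusted p = 1.03e-09, and adjusted p = 0.257 with an estimated correlation). The list has 40 members, and the filter, which a gene can pass on 1 library, removed those not tested. CALD1 and SPARC had no counts in the breast lines, and TPM2, VIM and SERPINE1 had at most 4 in any of them. These genes, all 3 past the threshold over all genes among them, passed the filter on MMNK-1 alone. Their direction was therefore fixed by the filter. The same holds for F3, MET and LDHB, named below. Past the threshold over all genes were CALD1, SPARC, which had 31 counts in MMNK-1, and the tropomyosin gene TPM2, with 38 counts against 1. None of them passed on summed transcripts (edgeR adjusted p of 0.0551 for CALD1, 0.182 for SPARC and 0.116 for TPM2), and over all alternative settings CALD1 passed in 13 of 15, SPARC in 10 of 14 and TPM2 in 11 of 14. Of the YAP and TGF-beta responsive genes 13 of 15 were higher, none past the threshold over all genes and 8 adjusted over the list alone (camera adjusted p = 7.76e-07). SERPINE1, an inhibitor of plasminogen activation, had 28 counts in MMNK-1 and 1 in the breast lines, and the tissue factor gene F3 had 24 and 2. SERPINE1 passed in edgeR with any 1 breast line left out (adjusted p = 0.000253 without MCF-7, 0.035 without T-47D and 0.0306 without ZR-75-1), and F3 without MCF-7 (0.0166) or ZR-75-1 (0.032). In the extracellular matrix list 9 of 10 were higher, and PLOD2, a collagen lysyl hydroxylase, had 853 CPM against 61.0 ± 27.7, the single member past the threshold (camera adjusted p = 0.00265). PLOD2 missed the threshold in 5 of 15 alternative settings, with adjusted p of 0.0516 to 0.185 (0.124 in edgeR on summed transcripts). Of the glycolysis and hypoxia genes 17 of 23 were higher, with the lactate dehydrogenase gene LDHB, at least 13.3-fold, the only one past the threshold (camera adjusted p = 0.00443). LDHB missed it in 3 of 14 settings, with adjusted p of 0.0758 to 0.428 (0.102 in edgeR on summed transcripts). The mitotic list (16 of 20 higher, camera adjusted p = 0.0129) and the receptor tyrosine kinases (3 of 4 higher, camera adjusted p = 0.0411) had no member past the threshold over all genes, although 2 kinases passed adjusted over the list alone. The kinase list missed the threshold in 8 of 10 alternative settings, with camera adjusted p of 0.0556 to 0.821, the highest on summed transcripts and the lowest without T-47D (0.0611 without ZR-75-1). The mitotic list missed it without MCF-7 (0.17) and with an estimated correlation (0.639). MET, the receptor of hepatocyte growth factor, had 21 counts in MMNK-1 and 2 in the breast lines, and passed in edgeR without MCF-7 (adjusted p = 0.0435).

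Lists of epithelial and luminal genes lay on the other side. In the epithelial junction list 15 of 18 tested members were lower in MMNK-1, 1 past the threshold over all genes and 8 adjusted over the list alone (camera adjusted p = 2.51e-05, and adjusted p = 0.257 with an estimated correlation). That member was SPINT1, a protease inhibitor, with 430 ± 125 CPM in the breast lines and 1 count in MMNK-1 (edgeR adjusted p = 0.0262, and 0.0741 on summed transcripts). Of the luminal breast genes 18 of 20 were lower, with KRT8 past the threshold over all genes and 9 genes adjusted over the list alone (camera adjusted p = 0.000122). All 23 oestrogen-responsive genes were lower, none past the threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 0.000161). The biliary epithelium list, which names the tissue of origin of MMNK-1, was lower as well: 13 of 14 members were lower than in the breast lines, CD24 past the threshold and 2 adjusted over the list alone (camera adjusted p = 0.00218, and adjusted p = 0.364 with an estimated correlation). Without counts in MMNK-1 were 7 of the 18 epithelial junction, 11 of the 20 luminal, 7 of the 23 oestrogen-responsive and 6 of the 14 biliary members. They passed the filter on breast lines alone, so their direction was fixed by it. Members with 1 count there, among them SPINT1, KRT7 and KRT19, did so too. With genes that had no counts in a group set to their bound, the median log2 fold change was 2.96 for the mesenchymal list, -2.44 for epithelial junctions, -2.08 for luminal genes, -2.17 for oestrogen-responsive genes and -1.17 for the biliary list.

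**Figure D2:**
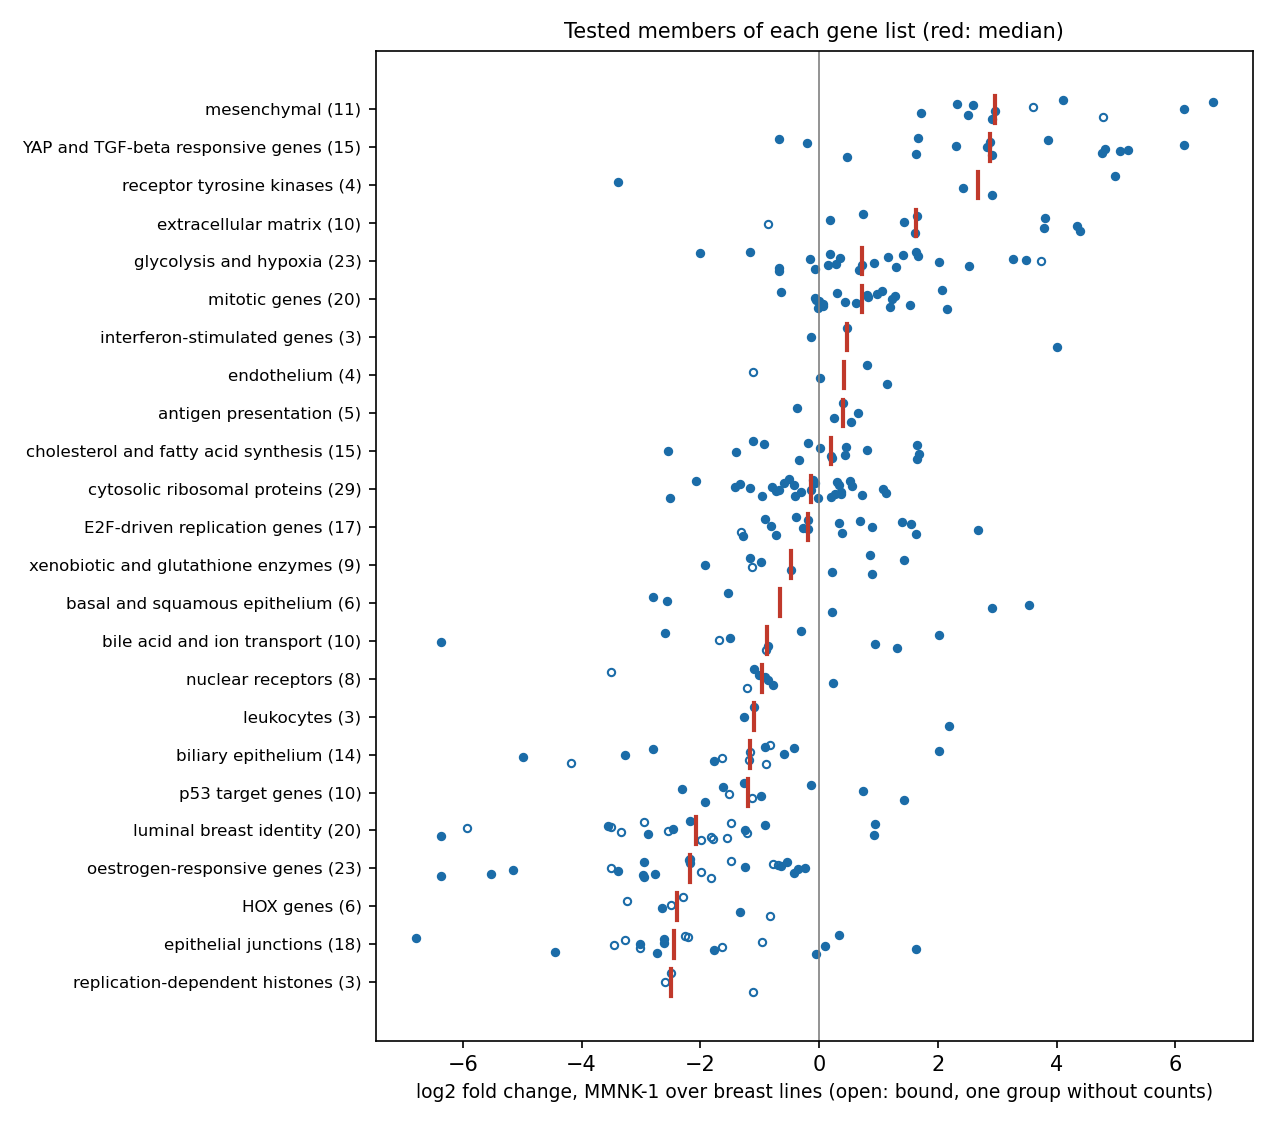
Log2 fold change of MMNK-1 over the breast lines (horizontal axis) for each tested member of the 24 lists with at least 3 tested genes, with the number tested in brackets and the median in red. Open points are bounds for genes without counts in a group, and the medians run from 2.96 in the mesenchymal list to -2.50 in the replication-dependent histones.

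The other lists did not pass. Nuclear receptors (7 of 8 lower, camera adjusted p = 0.133), HOX genes (6 of 6 lower, 0.0755) and replication-dependent histones (3 of 3 lower, 0.133) came nearest. In these lists 2, 4 and 3 members had no counts in MMNK-1 and passed the filter on breast lines alone, which fixed their direction. The camera adjusted p was 0.212 for interferon-stimulated genes, 0.442 for E2F-driven replication, 0.497 for antigen presentation, 0.601 for p53 targets, 0.707 for cholesterol and fatty acid synthesis, 0.742 for basal and squamous genes, 0.773 for xenobiotic and glutathione enzymes and 0.834 for bile acid and ion transport. It was 0.902 for the endothelial, leukocyte and ribosomal protein lists. None of these lists had a member past the threshold over all genes, although ITGA6, an integrin of the basal list, had 175 CPM in MMNK-1 against 14.9 ± 8.35 (edgeR adjusted p = 0.0833) and DDX58, an interferon-stimulated gene, 102 against 6.09 ± 3.26 (edgeR adjusted p = 0.0868). With a breast line left out, members of these lists passed in both directions. ITGA6, DDX58, FEN1, opposite TMEM258, and FADS2, opposite FADS1, were higher in MMNK-1. HOXC10, HOXC11, HIST1H2BK, HIST2H2AC, CA12 and PGR were lower. In the basal, E2F, xenobiotic and leukocyte lists the median was below 0 while camera pointed up, and in the endothelial list the mean was. The hepatocyte list and the list of NF-kB targets and cytokines had 2 tested genes each and the cancer-testis list 0, and no row carried the names used for the mitochondrially encoded genes.

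Of the 16 markers fixed in advance, KRT8 is described above. The progesterone receptor gene PGR had 15, 63 and 45 counts in MCF-7, T-47D and ZR-75-1 and 0 in MMNK-1, at least 11.4-fold lower (edgeR adjusted p = 0.0849). ESR1, the oestrogen receptor gene, had 12, 7 and 5 counts and 0 in MMNK-1, and the luminal transcription factor genes GATA3 (37, 17 and 5) and FOXA1 (49, 42 and 12) also had 0, with edgeR adjusted p of 0.417, 0.189 and 0.11. KRT19 had 122 ± 29.5 CPM in the breast lines and 1 count in MMNK-1 (adjusted p = 0.0972), KRT7 37.3 ± 8.26 CPM and 1 count (0.332), and EPCAM 32.9 ± 11.8 CPM and no counts (0.225). VIM itself had 30 counts in MMNK-1 and 1, 1 and 4 in the breast lines, a ratio of 17.8 (95% interval 7.29 to 52.3; adjusted p = 0.0848). Several of these genes passed with 1 breast line left out, PGR and FOXA1 whichever line it was. Each such fit called more genes in total than the main one. PGR passed in edgeR without MCF-7 (adjusted p = 0.000237), without T-47D (0.0427) and without ZR-75-1 (0.0264), and in 6 of 15 alternative settings in all, whose adjusted p ran from 0.000237 to 0.809. FOXA1 also passed without MCF-7 (0.00298), T-47D (0.0498) or ZR-75-1 (0.0156), and in 5 of 15 settings in all (0.00298 to 0.855). GATA3 passed without ZR-75-1 (0.0349), KRT19 without MCF-7 (0.00373) and VIM without MCF-7 (0.0133) or ZR-75-1 (0.0321), whereas ESR1, KRT7 and EPCAM passed in no setting. KRT18, opposite KRT8, had 158 CPM in MMNK-1 and 378 ± 300 in the breast lines, CDH1 87.7 and 90.7 ± 45.7, and SOX9 17.5 and 23.6 ± 20.7. ERBB2, opposite MIEN1 (6 counts in MMNK-1, 6 to 7 in the breast lines), EGFR (3 and 0), HNF1B (0 and at most 4) and ZEB1 (0 in all 4 libraries) had too few counts to be tested.

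Among the breast lines, which had 1 library each and hence no test, 71 rows were selective for MCF-7, 27 for T-47D and 21 for ZR-75-1, with at least 8 times the CPM of the higher of the other breast lines. In MCF-7 SULF2, opposite the oestrogen receptor coactivator gene NCOA3, had 3025 CPM (95% Poisson interval 2834 to 3226), 248 times the level in T-47D. FZD4, opposite the oestrogen-responsive protease gene PRSS23, had 3301 CPM (135 times), AP4B1, opposite DCLRE1B, 846 (92.6 times), the ubiquitin protease gene USP32 619 (67.8 times) and the transcription factor gene TBX2 535 (58.5 times). ZIC4, opposite ZIC1, had 105 counts in MCF-7 and none in any other library, at least 37.3 times the floor. T-47D was set apart by FAM228B, opposite the p53-inducible TP53I3, with 8684 CPM (95% Poisson interval 8368 to 9008; 54.7 times), and by the endothelin gene EDN1 with 5955 CPM (27.8 times). HOXB3 (576 CPM, 35.5 times), the calcium channel gene ITPR1 (524 CPM, 33.0 times), the melanosomal enzyme gene TYRP1 (298 CPM, at least 30.7 times) and the glutamate receptor gene GRIK1 (207 CPM, 21.3 times) followed. ZR-75-1 was set apart by SMAP2 at 325 CPM (33.4 times), GPATCH3, opposite NUDC, at 243 (25 times), the metalloprotease gene ADAMTS15 at 225 (23.1 times), CSMD3 at 140 (at least 14.4 times), CATSPER3 at 108 (11.1 times) and MPPE1, opposite GNAL, at 180 (11.1 times). Where a comparison line had fewer than 3 counts, the ratio is to the floor of 3.

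**Figure D3:**
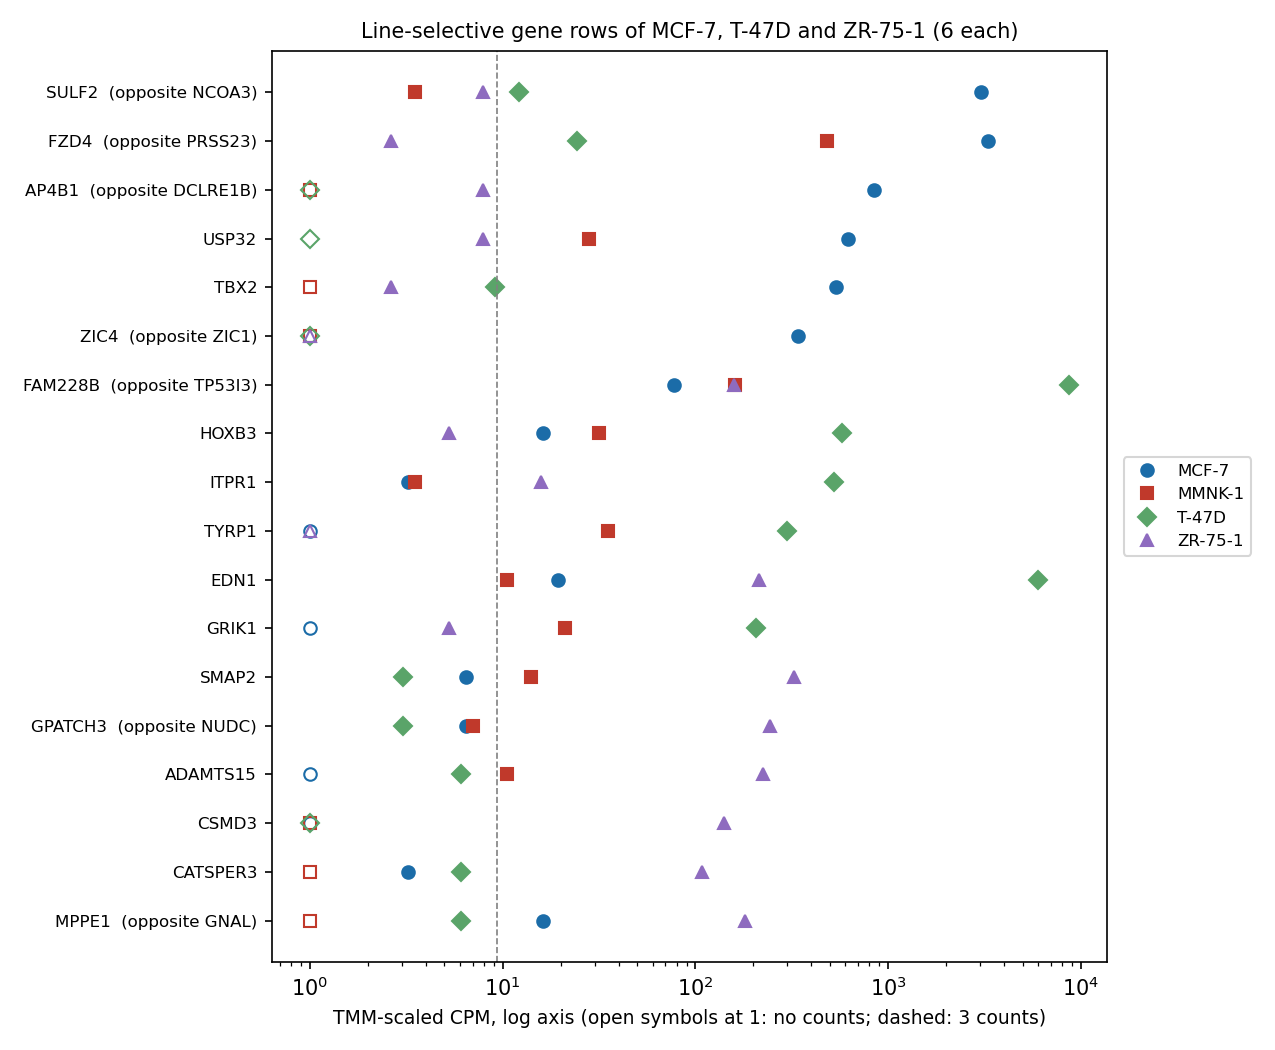
TMM-scaled CPM (log axis) in the 4 libraries for the 6 named line-selective rows of each breast line, MCF-7 at the top, T-47D in the middle and ZR-75-1 at the bottom. Each row is highest in its own line, from 108 CPM for CATSPER3 to 8684 CPM for FAM228B, and open symbols mark libraries without counts.

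Of 57 placements of 19 lists against 10000 random lists of the same size and expression, the oestrogen-responsive genes lay at the 99.7th percentile in MCF-7 and at the 0.40th in T-47D, with medians 0.81 above and 0.74 below the other breast lines on the log2 scale. The mitotic genes lay at the 0.07th percentile in MCF-7, with a median 1.12 below the others, and at the 99.9th in ZR-75-1, with a median 1.15 above them. The 6 HOX genes lay at the 100th percentile in T-47D, with a median 2.66 above the other lines. The percentiles describe these 3 libraries and were not tested.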

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

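Leaving out genes opposite coding exons was chosen after the data were seen, as was the highest transcript count as the main value, which turned the planned sum over transcripts into an alternative, and the other settings were chosen before. No paired analysis was possible because the groups share only 1 replicate number, which marks different cell lines. All 88 genes kept their direction in every setting that tested them (47 of them when genes opposite coding exons were left out), and the count stayed within 1.5 times of 88 with other scaling factors, a mean CPM of 1, robust hyperparameters, a test against a 2-fold change and transcripts as deposited.

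Without a filter 364 genes passed, 201 higher and 163 lower. With DESeq2 167 passed, 102 of them lower, with limma-voom 2, both higher and 0 lower (384 had an unadjusted p under 0.05), and with robust hyperparameters 40 were lower. After thinning to the shallowest library 47 passed, 36 higher and 11 lower. With summed transcripts 16 passed, 13 higher and 3 lower. With genes opposite coding exons left out, which leaves fewer genes to test, 37 passed, 32 higher and 5 lower. The share of higher genes among those called was 72.7%, and 73% and 74.7% with the other scaling factors. With a breast line left out 162 to 411 genes passed, 84 to 165 higher and 78 to 246 lower: 411 without MCF-7, 162 without T-47D and 204 without ZR-75-1. Of the 26 named genes that passed, 6 passed with summed transcripts, 0 with limma-voom, 15 after thinning, 20 against a 2-fold change and 25 or 26 with a breast line left out. Apart from the smaller number of genes, the cause of these differences was not tested.

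With an estimated correlation 0 lists were higher and 0 lower. In the other settings 5 or 6 lists were higher and 4 or 5 lower. The receptor tyrosine kinase list passed in 2 of 10 settings and missed in 8, with camera adjusted p of 0.821 on summed transcripts, 0.373 with a mean CPM of 1, 0.104 with genes opposite coding exons left out, 0.0648 with limma-voom weights and 0.0622 with a prior count of 0.5. The mitotic list passed in 8 of 10, and the other 8 lists in 9 of 10, all but that with an estimated correlation.

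KRT8 passed in 6 of 14 settings and missed with upper-quartile factors (adjusted p = 0.0512), a mean CPM of 1 (0.0836), a test against a 2-fold change (0.111), thinning (0.0642), limma-voom (0.218), transcripts as deposited (0.0872), summed transcripts and without ZR-75-1. Among markers short of the threshold, PGR passed without a filter (0.00449), with DESeq2 (0.0316), with robust hyperparameters (0.0497) and with any 1 breast line left out, and FOXA1 without a filter (0.00771), with DESeq2 (0.041) and with any 1 breast line left out. GATA3 and KRT19 passed in 2 of 15 settings and VIM in 4 of 14. The cause was not tested.

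The marker genes SOX9 and CDH1, neither past the threshold in any setting, changed sign. The log2 fold change of SOX9 was 0.55 with limma-voom and ran from -1.01 to 0.07 with a breast line left out, positive without MCF-7. That of CDH1 was 0.01 with upper-quartile factors, 0.06 with limma-voom and 0.02 after thinning, and ran from -0.31 to 0.45, positive without ZR-75-1. The cause was not tested.

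With a ratio of 4 in place of 8, 191 genes were selective for MCF-7, 125 for T-47D and 110 for ZR-75-1, and with a ratio of 16, 25, 11 and 4. With summed transcripts 49 were selective for T-47D and 42 for ZR-75-1, and with genes opposite coding exons left out 12 for ZR-75-1. Minimums of 5 and 20 CPM moved nothing, since 8 times the floor exceeds both.

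MMNK-1 was less similar to the breast lines than these were to each other in every setting. Its mean r with them was 0.479 with a pseudocount of 0.5, 0.596 with one of 5, 0.614 with a mean CPM of 1, 0.651 without a filter, 0.548 with summed transcripts and 0.263 with genes opposite coding exons left out. The mean among breast lines was 0.661 with Spearman's coefficient, 0.751 with a pseudocount of 5, 0.744 without a filter and 0.524 with genes opposite coding exons left out. Leaving out mitochondrially encoded genes was not run, since the files hold none under the names used.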

Other observations

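Of the tests in this part, only that of opposite-strand neighbours was chosen before its result was seen, and the others were chosen after. The gene lists were also read on the rows opposite their members, with percentiles among random lists that rest on few rows and on fitted folds. In the mesenchymal list 5 of 6 such rows were higher in MMNK-1, 4 of them past the threshold, and the median log2 fold change of 9.04 lay at the 100th percentile of random lists. The exception was ACTA2-AS1, with 3 counts in MMNK-1 and 9 to 86 in the breast lines. The higher rows other than VIM-AS1 passed the filter on MMNK-1 alone, which fixed their direction. In the extracellular matrix list COL4A2-AS1 was higher and LAMA5-AS1 lower past the threshold (median 2.27 over 4 rows, 99.6th percentile), and all 6 rows opposite HOX genes had negative fold changes, none past the threshold (edgeR adjusted p of 0.0814 to 0.76) and 3 of them without counts in MMNK-1. Other lists differed from their own rows: on the opposite rows the medians were 1.73 for xenobiotic and glutathione enzymes (3 rows, 98.5th percentile), 1.25 for E2F-driven replication (4 of 4 rows positive, 97.2nd) and 0.77 for ribosomal proteins (7 rows, 95.3rd), where those on the lists' own rows were -0.48, -0.19 and -0.13. The median was 2.09 for receptor tyrosine kinases (3 rows, 99.0th percentile), -1.25 for luminal genes (1 row positive and 2 negative, 11.7th), -9.63 for the single biliary row (0.27th) and -3.65 for the 2 epithelial junction rows (4.56th). The remaining lists lay between the 8.97th percentile, for nuclear receptors, and the 93.6th, for mitotic genes. The row of EGFR-AS1 held 127 counts in MMNK-1 and 3 to 20 in the breast lines (edgeR adjusted p = 0.103).

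Most counts lay on rows opposite coding exons, and a candidate explanation is that reads were counted on the strand opposite to the annotated transcript. Genes with isoforms both with and without opposite coding exons were compared where an isoform had at least 40 counts and the counts differed. In 184 of 210 (87.6%, exact 95% interval 82.4 to 91.8) the isoforms with such exons held more. A read counts in each transcript it overlaps, so an isoform with more exons can hold more whatever the strand. This share alone therefore does not decide. Counting without regard to strand is argued against by coding genes, which held at least as many counts as their noncoding antisense row in only 30.8% of 448 pairs, and shallow sequencing alone by the ribosomal protein rows, whose upper quartile lay at the 91.3rd percentile of coding rows. The explanation needs reads that carry strand. The labels name no kit that marks it, but the same pairs also argue against reads without strand, which would reach the coding rows as well. The median ratio of the coding to the antisense row was 0.124. The strand setting of the counting is not given, so the explanation was not checked at its source, and no biological explanation was tested. If it holds, counts on rows without an opposite coding gene, TERT and the markers included, may be reads from the other strand and not expression of the named gene. For rows higher in MMNK-1 without an opposite coding exon, neighbours were sought for the 32 found in the annotation. Of these 37.5% (exact 95% interval 21.1 to 56.3) had an opposite-strand coding gene within 10 kb. The share was 47.1% among all such tested rows (one-sided Fisher's exact p = 0.899). Neighbours were counted on either side of a row, whichever end faced it and whether or not they had counts. The comparison therefore cannot decide whether transcription past the end of a neighbour reached the 32.

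The list results in the report rest on the low counts of the lists' own rows. Over 1115 genes with both rows tested, the own and the opposite row had fold changes of the same sign in 61.0% (exact 95% interval 58.1 to 63.9, and 50.3% if unrelated). Coding genes opposite each other can enter this count more than once, so its interval is too narrow. Over the 201 genes with a noncoding opposite row the share was 65.7% (exact 95% interval 58.7 to 72.2). Reads of the same genes that reach both rows would give such shares, and other causes were not tested. On the opposite rows the median of the mesenchymal list exceeded that of the epithelial junction list by 12.68 on the log2 scale, which decides nothing: the second list has 2 such rows of opposite sign, NFATC3 (-8.17) and LOC100652770 (0.88), so NFATC3 alone makes its median negative, and most of the rows had prompted the test. Whether tissue of origin, immortalisation or medium lies behind these differences was not tested, since each differs along with the line.

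Rows selective for MCF-7 included 7 on chromosome 17, SKA2, RPS6KB1, USP32, BCAS3, TBX2-AS1, TBX2 and BRIP1, which raised the hypothesis of a copy number gain. Over all 69 placed rows, 22 had another within 0.1 to 5 Mb, and matched random sets had a median of 23 (95% range 14 to 33). The test thus gave no sign of clustering among MCF-7-selective rows as a whole, and it leaves a gain at a single place open.

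With each line in turn as the lone library, MMNK-1 gave 88 genes and the highest of the other splits 0, so 1 of the 4 splits gave as many. With 4 splits no share under 0.05 can be reached. In the other splits MMNK-1, the library least like the rest, was part of the larger group and would widen its spread. Fewer calls there were thus built in, and 88 against 0 is not independent support. DESeq2 gave 167 genes for MMNK-1 and 22, 2 and 6 for MCF-7, T-47D and ZR-75-1.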
